A study of Homo sapiens with 27 samples.

How the data were processed

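Total RNA of SK-N-BE(2)c cells was measured on 27 Illumina bead arrays, each carrying biotin-labelled cRNA of a single sample. The cells had been cultured in hypoxia with DMSO or PP242 for 24, 48 or 72 h, and a 0 h control was included. The deposited non-normalized table gives 1 signal intensity per probe and array for 48107 probes, as whole numbers on a linear scale, with no detection p-values, no negative control probes and no background subtraction visible in the values. A deposited value table holds intensity values of 27367 of these probes with a median of 109.561, on a linear scale, quantile normalized by the authors. Its values were within 2.12% of a quantile normalization of the same probes computed here, and each of its 27 columns matched its own array. Why those probes are listed is not stated. No column of sample values was left unmapped (0 columns).

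The comparisons start from the non-normalized table. Signals were background corrected by normexp with an offset of 16, transformed to log2 and quantile normalized over all 48107 probes. The plan asked for detection p-values, which these tables do not hold. A stand-in was computed from each array, whose background was taken as the mode of its signals (density bandwidth 1.5) with the SD of the signals mirrored from below the mode. Probes with a background p under 0.05 on at least 3 arrays were kept, 31241 in all. Of the 27367 probes of the value table, 23495 had 1 gene symbol, 1 had several and 3871 had none in the annotation used here, and symbols were updated through the gene identifier where the reference gene table held it (23471 probes, 0 symbols changed). Kept probes without a name (14822) entered the normalization but no gene count. Each gene was represented by its kept probe with the highest mean signal, which left 12637 genes, 9678 of them with 1 kept probe.

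Array medians of the deposited intensity lay between 98 and 113, background modes between 92.4 and 106, background SDs between 4.76 and 6.13, and single signals between 71 and 25918. Between 20729 and 22843 probes per array were above background. The number of arrays limits the precision.

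Group differences were fitted with limma 3.58.1 in R 4.3.3, with 1 linear model over the 7 groups, empirical Bayes moderation without trend, and Benjamini-Hochberg adjustment over all genes within a comparison at a threshold of 0.05. The comparisons were PP242 against DMSO at 24, 48 and 72 h, DMSO at each time against the 0 h control, DMSO at 72 h against 24 h, and the differences of the PP242 effect between each pair of times. SE is the moderated standard error of the log2 change. Gene lists were tested with camera at a preset correlation of 0.01, two-sided, adjusted over 19 lists within a comparison. The PP242 effect at one time was also correlated across genes with the hypoxia effect at another time, so that no array entered both effects, with a jackknife SE over arrays.

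The 19 lists, written from textbook knowledge, were glycolysis, the hypoxia response outside glycolysis, HIF subunits and regulators, angiogenic factors, MYC targets and ribosome biogenesis, cytosolic ribosomal proteins, cholesterol synthesis, fatty acid synthesis, ATF4 targets and amino acid synthesis, the unfolded protein response, DNA replication and G1/S, G2/M and mitosis, FOXO targets and receptor feedback, lysosome and autophagy, oxidative phosphorylation, sympathoadrenal and neuronal genes, mesenchymal and neural crest genes, p53 targets and apoptosis, and markers of Schwann, immune, endothelial and blood cells. Of the 19 genes in the last list, 9 were measured here above background. Lists can share genes, and VEGFA and ADM are in both the hypoxia and the angiogenic list, so these lists are not independent. The comparisons, tests, lists, alternatives and the rule for named genes were fixed before the data were examined, apart from the additions stated in the closing section.

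Genes were named by rule. EPAS1, HIF1A, ARNT, VEGFA, MYCN, MTOR, RPTOR, RICTOR and DDIT4 were always named. In each PP242 and each hypoxia comparison, the rule took the 6 largest rises and the 6 largest falls among genes with an adjusted p under 0.05, 1 symbol and no overlap between the arrays of both groups, passing over symbols starting with LOC or holding orf. It further took up to 4 members with the smallest p from each list, the 4 largest differences each way between PP242 effects, and 6 rises and 6 falls for DMSO at 72 h against 24 h. The text gives a selection of these genes.

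Samples carry the numbers 1 to 4 within a group. Whether a shared number pairs arrays was checked by the correlation of same-number arrays across genes after removal of group means. Every same-number pair exceeded 0.1 in 6 of the 7 comparisons between groups, where the lowest values lay between 0.124 and 0.206. The comparison of DMSO at 72 h with the control had a lowest value of 0.0982 and was not treated as paired. It lies just under the bound, and the comparison at 48 h, treated as paired, is not clearly better matched. In both, 2 of the 4 DMSO arrays correlated best with the control array of their own number. A block moved the count at 72 h from 3112 to 4357 genes, and the calls it changes there are not listed. Where the numbers pair the arrays, a fit with the sample number as a block is given beside each count it moves by over 1.5 times and each call it changes.

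The procedure was tested on simulated arrays, drawn from the mean and spread of each probe with independent noise. Known changes were added to the simulated PP242 arrays at 72 h, in genes that were not among the dimmest. No other group difference, effect of the sample number or correlation between genes was simulated, so recovery in the real data can differ. The procedure recovered 18 of 67 genes changed by 0.5 (26.9%), 55 of 67 changed by 1 (82.1%) and 64 of 66 changed by 2 on the log2 scale (97.0%), and 11 unchanged genes were called, 7.43% of all calls.

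The alternatives were array weights, no background correction, an offset of 50, one median per array in place of quantile normalization, the authors' value table, no filter, a strict filter (p under 0.01 on every array of a group, 17942 probes), every kept probe, the mean of the kept probes of a gene, the sample number as a block, a fit of only the groups compared, eBayes with trend and robust estimation, camera with an estimated correlation, fry in place of camera, and leaving out each array in turn. A fit with the slide as a block was planned and not run, since the slide of each array is not given.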

Results

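Gene expression was measured in SK-N-BE(2)c cells, a human neuroblastoma line with amplified MYCN, on 27 Illumina bead arrays. The cells were kept in hypoxia with PP242, an ATP-competitive inhibitor of the mTOR kinase that acts on both mTOR complexes, or with the solvent DMSO. PP242 was measured at 24, 48 and 72 h with 4 arrays each, DMSO at 48 and 72 h with 4 arrays each and at 24 h with 3 arrays, and a 0 h control with 4 arrays. The label of the control states neither DMSO nor a time in hypoxia, so hypoxia, DMSO and time in culture are not separable in comparisons with it. The replicates are not said to be separate cultures, so p-values measure the spread between samples, which can be technical. The background level per array lay between 92.4 and 106 in intensity, and 20729 to 22843 probes per array were above background. Arrays with the same sample number resembled each other across groups, with 4565 genes differing between the numbers 4 and 1, 2102 between 3 and 1 and 94 between 2 and 1. No DMSO array at 24 h carries the number 4. Values below are log2 changes unless a unit is given.

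After 24 h of hypoxia, DMSO cells had raised genes of glycolysis and the wider hypoxia response relative to the 0 h control. The largest rises were those of the stress hormone gene CRH (4.24, SE 0.36, adjusted p = 5.71e-09), of COXFA4L2, a mitochondrial protein induced by HIF (3.82, SE 0.50), and of NDRG1, a hypoxia-responsive gene (3.67, SE 0.27). PFKFB3 (3.46) and PFKFB4 (3.16), which make an activator of glycolysis, and the mitochondrial adenylate kinase AK4 (3.13) followed. Of the 12637 genes tested, 105 rose and 23 fell, and 52 of the rises and 2 of the falls were at least 2-fold. The quinone reductase NQO1 fell by 1.34 (SE 0.14, adjusted p = 2.99e-07) and FAM217B fell by 0.91. COXFA4L2 was above background on 2 of the 4 control arrays, which holds for each comparison with the control.

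Glycolysis genes rose as a list at 24 h (median 1.29, camera adjusted p = 1.30e-40), with 13 of 20 members rising (17 adjusted over the list alone), among them the aldolases ALDOC (2.45) and ALDOA (1.61). The hypoxia response outside glycolysis rose by a median of 1.57 (adjusted p = 5.09e-61), with 20 of 29 members up (23 adjusted over the list alone), including BNIP3, a mitophagy receptor (2.51), and the collagen hydroxylase P4HA1 (2.46). ATF4 targets and amino acid synthesis genes rose with a median of 0.28 (adjusted p = 2.65e-08), and 4 of 31 members passed (8 adjusted over the list alone), such as the secreted glycoprotein STC2 (1.67) and the serine-glycine enzyme SHMT2 (1.11). These 3 lists also passed with an estimated correlation. Angiogenic factors rose (median 0.18, adjusted p = 0.00426; adjusted p = 0.0582 with an estimated correlation), with 2 of 13 members up (3 adjusted over the list alone), VEGFA by 2.09 and the vasodilator peptide ADM by 1.34. Both genes are also members of the hypoxia list.

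A further 3 lists passed weakly at 24 h. Cytosolic ribosomal proteins were higher as a list (median 0.11, adjusted p = 0.0116; adjusted p = 0.253 with an estimated correlation), though 0 of 27 members passed singly (0 adjusted over the list alone). Without control array 4 it had an adjusted p of 0.129. Cholesterol synthesis was higher (median 0.12, adjusted p = 0.0291; adjusted p = 0.312 with an estimated correlation) with 0 of 17 members passing, 4 adjusted over the list alone and 3 with the sample number as a block. It had an adjusted p of 0.198 without DMSO 24 h array 2. The p53 target list was lower (median -0.30, adjusted p = 0.0440; adjusted p = 0.312 with an estimated correlation). Its adjusted p was 0.313 without control array 4, 0.0622 without DMSO 24 h array 1 and 0.0775 without DMSO 24 h array 2. Of its 13 members 1 rose and 0 fell (1 and 1 adjusted over the list alone).

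The remaining 12 lists had adjusted p between 0.0524 and 0.880 at 24 h. Sympathoadrenal and neuronal genes had a median of 0.14 (adjusted p = 0.0524, and 0.0486 with the sample number as a block), and 1 of 23 members rose (6 up and 3 down adjusted over the list alone, 2 up and 1 down with the block), the catecholamine enzyme TH by 1.09. The DNA replication list had a median of -0.10 (adjusted p = 0.536) and the mitosis list one of 0.12 (adjusted p = 0.339). Median and mean differed in sign for HIF subunits and regulators (-0.13 and 0.04), MYC targets (-0.04 and 0.03), mesenchymal genes (-0.02 and 0.03), FOXO targets (-0.00013 and 0.01) and the markers of other cell types (0.02 and -0.14, adjusted p = 0.513). The last list had 1 of 9 members lower, the smooth muscle actin ACTA2 (-1.46, adjusted p = 0.00476), which had an adjusted p of 0.0595 without DMSO 24 h array 3. The gene count of 128 became 361 with the sample number as a block, 82 without DMSO 24 h array 2 and 80 without DMSO 24 h array 3.

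At 48 h of hypoxia the DMSO cells had higher glycolysis and hypoxia genes than the 0 h control, and MYC targets had fallen. COXFA4L2 rose by 5.54 (SE 0.46, adjusted p = 9.54e-10), NDRG1 by 5.44 (SE 0.25), CRH by 5.16, the metallothionein MT1G by 4.50, PFKFB3 by 4.28 and PFKFB4 by 3.95. The largest falls were those of CDC25A, a phosphatase that activates cyclin-dependent kinases (-1.61, SE 0.29, adjusted p = 0.000219), TACC1 (-1.61), NQO1 (-1.57), the flap endonuclease FEN1 (-1.57), AUNIP (-1.54) and the cell cycle transcription factor E2F2 (-1.53). In all 850 genes rose and 900 fell, with 166 and 65 of these at least 2-fold. The count of 1750 became 2988 with the sample number as a block. With one median per array the rising share went from 48.6% to 29.4% (495 up and 1188 down).

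Of the glycolysis genes 17 of 20 rose at 48 h (18 adjusted over the list alone, median 1.21, adjusted p = 4.64e-28), among them ALDOC (2.86) and the glucose transporter SLC2A1 (2.75). The wider hypoxia response had 24 of 29 members up (24 adjusted over the list alone, median 2.14, adjusted p = 9.30e-45), including AK4 (3.62) and P4HA1 (3.04). Of the angiogenic factors 5 of 13 rose (5 adjusted over the list alone, median 0.13, adjusted p = 0.000191), VEGFA by 3.61, ADM by 2.19 and the ephrin EFNA1 by 1.03. ATF4 targets had 12 of 31 members up (14 up and 1 down adjusted over the list alone, median 0.36, adjusted p = 5.05e-09), such as the stress transcription factor DDIT3 (2.50), STC2 (2.07) and SHMT2 (1.41). MYC targets and ribosome biogenesis genes fell, 9 of 23 (10 adjusted over the list alone, median -0.31, adjusted p = 0.000259), among them the ribosome assembly factor MRTO4 (-0.76) and PA2G4 (-0.66). All 5 of these lists passed with an estimated correlation.

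DNA replication genes fell at 48 h, 20 of 27 (24 adjusted over the list alone, median -0.79, adjusted p = 1.89e-14; adjusted p = 0.0594 with an estimated correlation), including the chromatin assembly subunits CHAF1B (-1.18) and CHAF1A (-1.03) and the replicative helicase subunit GINS3 (-1.01). The mitosis list had 0 of 30 members past the threshold (2 with the sample number as a block) and a median of -0.12 (adjusted p = 0.335). Cytosolic ribosomal proteins rose as a list (median 0.11, adjusted p = 0.0133; adjusted p = 0.226 with an estimated correlation), with 5 of 27 up (5 adjusted over the list alone), such as RPL37 (1.07) and RPL13A (0.71). The list had an adjusted p of 0.127 without control array 4.

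A block on the sample number changed 3 list calls at 48 h. Sympathoadrenal genes (adjusted p = 0.0580, blocked 0.0481) had 7 members up and 3 down of 23 (7 and 4 adjusted over the list alone), with TH (1.36), the neuronal protein MAP2 (1.06) and the granin CHGB (0.82) higher. Mesenchymal and neural crest genes (adjusted p = 0.0655, blocked 0.0481) had 5 of 17 up (5 adjusted over the list alone), with ID1 at 0.98. The p53 targets (adjusted p = 0.0655, blocked 0.0406) had 2 up and 4 down of 13 (2 up and 7 down adjusted over the list alone; 2 up and 8 down with the block), with the death receptor TNFRSF10B (1.73) and the cytokine GDF15 (1.46) higher and TP53I3 (-1.13) lower. The markers of other cell types had 0 of 9 members changed (adjusted p = 0.876). Signs differed between median, mean and test for HIF subunits (-0.09, 0.13, up), lysosome genes (0.04, -0.0023, up) and oxidative phosphorylation (0.06, 0.03, down), with adjusted p of 0.992 for each.

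By 72 h of hypoxia genes of DNA replication had fallen against the 0 h control, and the hypoxia genes were high. COXFA4L2 was up by 6.19 (SE 0.46, adjusted p = 7.39e-11), CRH by 5.55 (SE 0.34), NDRG1 by 5.52, MT1G by 4.77, PFKFB3 by 4.03 and VEGFA by 3.93. The largest falls were those of FEN1 (-2.63, SE 0.27, adjusted p = 4.22e-08), E2F2 (-2.62), CDC25A (-2.38), BRI3BP (-2.37), the replication initiation factor MCM10 (-2.29) and CHAF1B (-2.28). Altogether 1422 genes rose and 1690 fell, of which 285 and 318 by at least 2-fold. The rising share went, with one median per array, from 45.7% to 29.2% (895 up and 2173 down).

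DNA replication genes fell in 25 of 27 cases at 72 h (25 adjusted over the list alone, median -1.53, adjusted p = 4.56e-23). Mitosis genes fell in 24 of 30 (26 adjusted over the list alone, median -0.99, adjusted p = 5.29e-13; adjusted p = 0.124 with an estimated correlation), among them the survivin gene BIRC5 (-1.58), NUSAP1 (-1.42) and the kinase AURKA (-1.35). MYC targets fell in 11 of 23 (13 adjusted over the list alone, median -0.36, adjusted p = 0.000242), including PPAN (-1.04). Cytosolic ribosomal proteins rose in 10 of 27 (10 adjusted over the list alone, median 0.23, adjusted p = 6.28e-05), with RPL37 at 2.12 and RPL13 at 1.22. Glycolysis had 16 of 20 members up (17 adjusted over the list alone, median 1.01, adjusted p = 3.85e-16), among them SLC2A1 (2.62) and the hexokinase HK2 (2.56). The hypoxia response had 23 of 29 up (23 adjusted over the list alone, median 2.21, adjusted p = 5.09e-29), with the repressor BHLHE40 at 3.30. ATF4 targets had 12 up and 1 down of 31 (14 and 1 adjusted over the list alone, median 0.32, adjusted p = 4.87e-08), DDIT3 at 2.68 and STC2 at 2.36. Angiogenic factors had 4 of 13 up (4 adjusted over the list alone, median 0.08, adjusted p = 0.00485; adjusted p = 0.0511 with an estimated correlation), with EFNA1 at 1.69. All of these but mitosis and angiogenic factors passed with an estimated correlation.

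Among the 11 lists not called at 72 h (adjusted p 0.0980 to 0.955), members went both ways. The unfolded protein response had 5 up and 1 down of 13 (5 and 1 adjusted over the list alone, adjusted p = 0.0980), with the chaperone DNAJB9 at 1.09. The p53 targets had 2 up and 6 down of 13 (3 and 6 adjusted over the list alone, adjusted p = 0.412), with GDF15 (2.45) and TNFRSF10B (2.37) up and TP53I3 (-1.10) down, and a median of -0.27 against a mean of 0.0056. GDF15 was above background on 1 of the 4 control arrays, also in the comparison at 48 h. Sympathoadrenal genes had 7 up and 5 down of 23 (9 and 7 adjusted over the list alone, adjusted p = 0.362), with TH (1.49) and GATA3 (0.87) higher and the neurofilament NEFM (-0.91) and the receptor RET (-0.72) lower. Fatty acid synthesis had 3 up and 3 down of 12 (3 and 3 adjusted over the list alone, adjusted p = 0.741), and cholesterol synthesis 1 up and 4 down of 17 (1 and 5 adjusted over the list alone, adjusted p = 0.412). The other-cell markers had 1 of 9 lower, the monocyte marker CD14 (-0.65; list adjusted p = 0.955).

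Between 24 and 72 h of hypoxia, both in DMSO, genes of DNA replication and MYC targets fell. The largest rises were those of ZNF467 (3.34, SE 0.16, adjusted p = 5.74e-14), MT1G (3.23), the activity-regulated NPAS4 (2.99), the stress transcription factors ATF5 (2.74) and DDIT3 (2.60), and MT1E (2.56). NPAS4 was above background on 1 of the 3 arrays at 24 h. The falls were led by FEN1 (-2.45, SE 0.30, adjusted p = 1.68e-06), the thioredoxin-binding protein TXNIP (-2.34), the thymidine kinase TK1 (-2.3005), the polymerase subunit POLE2 (-2.24), MCM10 (-2.20) and UHRF1 (-2.12). In all 989 genes rose and 1109 fell, 175 and 265 of them at least 2-fold. The count of 2098 became 3203 with the sample number as a block and 1360 without DMSO 24 h array 2. With one median per array the rising share went from 47.1% to 23.5% (542 up and 1766 down).

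In this comparison of times DNA replication genes fell in 26 of 27 cases (26 adjusted over the list alone, median -1.503, adjusted p = 5.49e-28), and MYC targets in 7 of 23 (12 adjusted over the list alone and 12 with the sample number as a block, median -0.42, adjusted p = 1.63e-05). Both lists passed with an estimated correlation. Mitosis genes fell in 25 of 30 (30 adjusted over the list alone, median -1.05, adjusted p = 4.66e-18; adjusted p = 0.141 with an estimated correlation). Cholesterol synthesis fell, with 7 down and 1 up of 17 (8 and 1 adjusted over the list alone, median -0.40, adjusted p = 0.0106; adjusted p = 0.322 with an estimated correlation). The hypoxia response rose further, with 10 up and 1 down of 29 (11 and 1 adjusted over the list alone, median 0.33, adjusted p = 0.000324; adjusted p = 0.194 with an estimated correlation). Cytosolic ribosomal proteins rose in 4 of 27 (4 adjusted over the list alone, 8 with the block, median 0.12, adjusted p = 0.00675; adjusted p = 0.2498 with an estimated correlation). ATF4 targets rose with 9 up and 2 down of 31 (10 and 3 adjusted over the list alone, median 0.17, adjusted p = 0.00717; adjusted p = 0.322 with an estimated correlation). With arrays scaled to one median its median was -0.01 (adjusted p = 0.0617). Oxidative phosphorylation was lower, with 2 of 26 down (1 adjusted over the list alone, 5 with the block, median -0.18, adjusted p = 0.0280; adjusted p = 0.608 with an estimated correlation). It had an adjusted p of 0.145 under the block, 0.0734 without DMSO 24 h array 1 and 0.0787 without DMSO 72 h array 4.

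PP242 at 24 h lowered genes of cell division, cholesterol synthesis and glycolysis, relative to DMSO at the same time. The mitotic kinase genes CDK1 (-3.33, SE 0.56, adjusted p = 7.69e-05) and PBK (-3.17, SE 0.31) fell, as did MELK (-3.08), the centromeric histone CENPA (-2.89), TK1 (-2.87) and BIRC5 (-2.83). The transcription factor KLF2 rose by 3.92 (SE 0.31, adjusted p = 1.31e-08), the immediate early gene EGR1 by 3.06 (SE 0.31), TGFB1I1 by 2.34, ZNF581 by 2.15, CLIP3 by 2.05 and EPB41L4A-AS1 by 1.85. In all 1312 genes rose and 1429 fell, 213 and 388 of them at least 2-fold. The rising share went, with one median per array, from 47.9% to 23.8% (662 up and 2120 down).

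All 30 measured mitosis genes fell with PP242 at 24 h (30 adjusted over the list alone, median -1.98, adjusted p = 2.16e-34), among them AURKA (-2.42) and cyclin B, CCNB1 (-2.21). DNA replication genes fell in 26 of 27 cases (26 adjusted over the list alone, median -1.52, adjusted p = 1.16e-27), with E2F2 at -2.81, MCM10 at -2.65 and CHAF1B at -1.87. Cholesterol synthesis fell, with 10 down and 1 up of 17 (10 and 1 adjusted over the list alone, median -0.88, adjusted p = 2.25e-07), including ACAT2 (-2.79), MSMO1 (-1.93) and HMGCS1 (-1.76). Glycolysis genes fell in 11 of 20 cases (14 adjusted over the list alone, median -0.62, adjusted p = 4.18e-07), such as ALDOC (-1.64), PFKFB3 (-1.48) and SLC2A1 (-1.46). These 4 lists passed with an estimated correlation.

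A further 5 lists were lower at 24 h of PP242 and did not pass with an estimated correlation. ATF4 targets had 14 down and 3 up of 31 (15 and 4 adjusted over the list alone, median -0.33, adjusted p = 0.000270; adjusted p = 0.177 with an estimated correlation), with the amino acid transporter chains SLC3A2 at -1.48 and SLC7A5 at -1.05 and the serine synthesis enzyme PHGDH at -1.24. The unfolded protein response had 10 of 13 down (10 down and 1 up adjusted over the list alone, median -0.71, adjusted p = 0.000270; adjusted p = 0.0806 with an estimated correlation), including SDF2L1 (-1.62) and CRELD2 (-1.11). The hypoxia response had 10 down and 1 up of 29 (11 and 1 adjusted over the list alone, median -0.27, adjusted p = 0.00420; adjusted p = 0.208 with an estimated correlation), with ADM at -1.62, FAM162A at -1.54 and AK4 at -1.13. Oxidative phosphorylation had 9 of 26 down (10 adjusted over the list alone, median -0.36, adjusted p = 0.000457; adjusted p = 0.305 with an estimated correlation), such as NDUFA8 (-0.69). Number 4 arrays, absent from DMSO at 24 h, were lower than number 1 arrays in this list by a median of -0.42. Mesenchymal genes had 6 of 17 down (6 down and 1 up adjusted over the list alone, median -0.21, adjusted p = 0.0427; adjusted p = 0.208 with an estimated correlation), with SNAI2 at -1.20 (above background on 2 of the 4 PP242 arrays) and TWIST1 at -0.62. That call ended with the sample number as a block (adjusted p = 0.0582), with one median per array (0.0676), without PP242 24 h array 3 (0.0537) and without PP242 24 h array 4 (0.0555).

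The other 10 lists were not called at 24 h of PP242 (adjusted p 0.0530 to 0.993). FOXO targets and receptor feedback genes had 6 up and 5 down of 19 (6 and 5 adjusted over the list alone, adjusted p = 0.661), with TXNIP (1.61), the insulin receptor substrate IRS2 (1.52) and FOXO3 (1.47) higher, and a median of -0.10 against a mean of 0.16. Lysosome and autophagy genes had 4 up and 2 down of 29 (4 and 2 adjusted over the list alone, adjusted p = 0.799), with the autophagy kinase ULK1 at 1.08 and the galactosidase GLA at -1.73. Fatty acid synthesis had 4 of 12 down (4 down and 1 up adjusted over the list alone, adjusted p = 0.0530), including the lipid regulator SREBF1 (-0.94). Cytosolic ribosomal proteins had 3 of 27 up (3 adjusted over the list alone, adjusted p = 0.137), with RPL37 at 1.83 and RPL22 at 0.89. Sympathoadrenal genes had 6 up and 3 down of 23 (6 and 3 adjusted over the list alone, adjusted p = 0.413), with GATA2 at 0.98 and NEFM at -0.94. The p53 list had 1 up and 3 down of 13 (2 and 4 adjusted over the list alone, adjusted p = 0.870, median 0.04, mean 0.0041, test direction down), with the apoptosis inhibitor BCL2 at 1.33 and the apoptosis promoter PMAIP1 at -1.20. HIF subunits had 0 of 8 members changed (0 adjusted over the list alone, 1 up and 3 down with the block), with a median of 0.05 and a mean of -0.05 (adjusted p = 0.993). The other-cell markers had 3 of 9 down (3 adjusted over the list alone, median -0.04, adjusted p = 0.148), DCN at -1.38, LUM at -1.33 and CD14 at -0.90, beside the mesenchymal fall.

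At 48 h PP242 lowered genes of the hypoxia response, glycolysis and angiogenesis, relative to DMSO. The largest falls were those of IGFBP5, which binds insulin-like growth factors (-3.31, SE 0.19, adjusted p = 7.85e-12), and the calcium-binding S100A4 (-3.10, SE 0.25). COXFA4L2 (-2.68), the phosphodiesterase PDE4C (-2.63), the serotonin receptor HTR3A (-2.56) and the proteoglycan DCN (-2.55) followed. PDE4C was above background on 2 of the 4 PP242 arrays. KLF2 rose by 3.96 (SE 0.29, adjusted p = 4.43e-10), EGR1 by 3.46 (SE 0.29), TXNIP by 3.07, COL22A1 by 1.87, the neuropeptide precursor VGF by 1.76 and the tubulin TUBB2A by 1.68. In all 560 genes rose and 731 fell, 58 and 137 of them at least 2-fold. The count of 1291 became 2506 with the sample number as a block. With one median per array the rising share went from 43.4% to 19.6% (236 up and 967 down).

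The hypoxia response fell in 14 of 29 members at 48 h of PP242 (18 adjusted over the list alone, median -0.47, adjusted p = 2.60e-15), including ADM (-2.02), BHLHE40 (-1.79) and FAM162A (-1.55). Glycolysis fell in 11 of 20 (14 adjusted over the list alone, median -0.57, adjusted p = 1.71e-12), with SLC2A1 at -2.07 and PFKFB4 at -1.78. ATF4 targets had 12 down and 1 up of 31 (14 and 1 adjusted over the list alone, median -0.42, adjusted p = 5.93e-08), such as DDIT3 (-2.02), PHGDH (-1.25) and SHMT2 (-0.91). Angiogenic factors fell in 6 of 13 (6 down and 1 up adjusted over the list alone, median -0.23, adjusted p = 5.45e-05), with the placental growth factor PGF at -1.32 and EFNB2 at -1.27. Mesenchymal genes fell in 5 of 17 (7 adjusted over the list alone, 8 with the sample number as a block, median -0.15, adjusted p = 0.000148), with TWIST1 at -1.35 and ID1 at -1.33. The markers of other cell types fell with them, 3 of 9 (3 adjusted over the list alone, median -0.11, adjusted p = 0.00287), through DCN, ACTA2 (-2.03) and LUM (-1.45), genes of the extracellular matrix and of contraction. LUM was above background on 2 of the 4 PP242 arrays. All 6 lists passed with an estimated correlation.

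Mitosis genes fell in 22 of 30 cases at 48 h of PP242 (26 adjusted over the list alone, median -0.88, adjusted p = 1.33e-17; adjusted p = 0.0618 with an estimated correlation), such as AURKA (-1.24) and PLK1 (-1.10). DNA replication was lower as a list (median -0.23, adjusted p = 0.0253; adjusted p = 0.596 with an estimated correlation) with 0 of 27 members passing (0 adjusted over the list alone, 3 with the block). Its adjusted p was 0.0726 without DMSO 48 h array 2, 0.282 without DMSO 48 h array 4 and 0.626 without PP242 48 h array 1. Oxidative phosphorylation had 4 of 26 down (5 down and 1 up adjusted over the list alone, 7 down and 1 up with the block, median -0.32, adjusted p = 0.00620; adjusted p = 0.437 with an estimated correlation). Cholesterol synthesis had 2 of 17 down (2 adjusted over the list alone, 7 with the block, median -0.31, adjusted p = 0.0124; adjusted p = 0.245 with an estimated correlation), with EBP at -0.66 and STARD4 at -0.81. The list had an adjusted p of 0.0510 without DMSO 48 h array 4 and 0.0740 without PP242 48 h array 1. Cytosolic ribosomal proteins rose in 4 of 27 (6 adjusted over the list alone, 7 with the block, median 0.13, adjusted p = 0.000589; adjusted p = 0.0762 with an estimated correlation), with RPL37 at 1.44 and RPL22 at 0.80. The other kept probe of RPL37 had no change at an unadjusted p under 0.05.

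Of the 8 lists not called at 48 h of PP242 (adjusted p 0.0711 to 0.875), FOXO targets had 4 up and 4 down of 19 (4 and 4 adjusted over the list alone, adjusted p = 0.630), with IRS2 (1.53) and KLF6 (1.22) higher, the stress protein SESN3 lower (-0.97), and a median of -0.03 against a mean of 0.17. Sympathoadrenal genes had 3 up and 2 down of 23 (4 and 2 adjusted over the list alone, adjusted p = 0.308), with the neuronal RNA-binding protein ELAVL4 at 1.03 and RET at 0.88. The autophagosome protein MAP1LC3B rose by 0.76 among 3 up and 1 down of 29 lysosome genes (3 and 2 adjusted over the list alone, adjusted p = 0.630), where a block gave 3 up and 5 down. MYC targets had 1 of 23 up (1 adjusted over the list alone, 3 with the block, adjusted p = 0.0711), and the unfolded protein response 0 of 13 (0 adjusted over the list alone, 1 up and 1 down with the block, adjusted p = 0.630).

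At 72 h PP242 lowered genes of the hypoxia response, glycolysis and angiogenesis and ATF4 targets, relative to DMSO. COXFA4L2 (-3.59, SE 0.46, adjusted p = 4.10e-06), IGFBP5 (-3.26, SE 0.19), MT1G (-3.05), ATF5 (-2.78), ZNF467 (-2.75) and DDIT3 (-2.69) fell. KLF2 rose by 3.40 (SE 0.29, adjusted p = 5.15e-09), TXNIP by 3.34 (SE 0.21), EGR1 by 3.10, ADGRG2 by 2.11, NAV2 by 2.00 and the kinase SGK1 by 1.80. In all 432 genes rose and 692 fell, 62 and 154 of them at least 2-fold. The count of 1124 became 2164 with the sample number as a block. Scaled to one median per array, 243 genes rose and 591 fell, and the rising share went from 38.4% to 29.1%.

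ATF4 targets fell in 14 of 31 members at 72 h of PP242 (18 down and 1 up adjusted over the list alone, median -0.55, adjusted p = 9.39e-15), among them the pseudokinase TRIB3 (-2.11) and CEBPB (-1.35). The hypoxia response fell in 15 of 29 (17 down and 2 up adjusted over the list alone, median -0.71, adjusted p = 7.30e-14), with BHLHE40 at -2.12 and NDRG1 at -1.83. Glycolysis fell in 10 of 20 (10 adjusted over the list alone, median -0.58, adjusted p = 4.79e-09), with SLC2A1 at -1.88 and HK2 at -1.24. Angiogenic factors had 5 down and 1 up of 13 (7 and 1 adjusted over the list alone, median -0.36, adjusted p = 1.29e-05), with ADM at -2.02 and EFNA1 at -1.21. These 4 lists passed with an estimated correlation.

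DNA replication genes rose in 12 of 27 cases at 72 h of PP242 (17 adjusted over the list alone, median 0.66, adjusted p = 2.52e-11; adjusted p = 0.0783 with an estimated correlation), FEN1 by 1.29 and GINS2 by 1.02. The mitosis list was higher (median 0.23, adjusted p = 0.0110; adjusted p = 0.762 with an estimated correlation) with 0 of 30 members passing (0 adjusted over the list alone, 3 with the block). Its adjusted p was 0.0747 without DMSO 72 h array 1 and 0.340 without PP242 72 h array 2. Sympathoadrenal genes were higher, with 6 up and 3 down of 23 (8 and 4 adjusted over the list alone, median 0.09, adjusted p = 0.0444; adjusted p = 0.0666 with an estimated correlation), among them ELAVL4 (1.07), RET (1.02) and the growth cone protein GAP43 (0.68). That call ended without DMSO 72 h arrays 1 (0.0629), 2 (0.0560) or 4 (0.0508) and without PP242 72 h array 1 (0.0762). The unfolded protein response had 2 of 13 down (4 adjusted over the list alone, 5 with the block, median -0.26, adjusted p = 0.00134; adjusted p = 0.0783 with an estimated correlation), with the chaperone HYOU1 at -0.73. Mesenchymal genes had 4 of 17 down (8 down and 1 up adjusted over the list alone, 7 down and 1 up with the block, median -0.33, adjusted p = 0.00217; adjusted p = 0.0675 with an estimated correlation), with TWIST1 at -0.98 and ID1 at -0.88. Other-cell markers had 2 of 9 down (2 adjusted over the list alone, median -0.09, adjusted p = 0.0171; adjusted p = 0.0572 with an estimated correlation), DCN, at least 4.56-fold lower since no PP242 array was above background, and ACTA2 (-2.07). Without PP242 72 h array 3 the list had an adjusted p of 0.0613.

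Oxidative phosphorylation had 1 of 26 members up at 72 h of PP242 (1 adjusted over the list alone, 2 up and 2 down with the block) and a median of -0.19 (adjusted p = 0.146, blocked 0.0408). The other 8 lists had adjusted p between 0.114 and 0.873. The FOXO list had 3 up and 3 down of 19 (3 and 5 adjusted over the list alone, adjusted p = 0.764), TXNIP and IRS2 (1.03) up and SESN3 (-1.66, above background on 2 of the 4 PP242 arrays) down, with a median of -0.00068 and a mean of 0.12. Lysosome genes had 2 up and 2 down of 29 (2 and 2 adjusted over the list alone, 3 up and 4 down with the block, adjusted p = 0.873), with the mTORC1 regulator FLCN at -1.08 and UVRAG at -0.63, and a median of 0.03 against a mean of -0.02. The p53 list had 1 up and 2 down of 13 (2 and 2 adjusted over the list alone, adjusted p = 0.764, median 0.03, mean -0.16), with GDF15 at least 4.30-fold lower, TNFRSF10B at -0.93 and BCL2 at 0.72 (adjusted p = 0.0317). The call of BCL2 ended without DMSO 72 h arrays 1 (0.109), 2 (0.0772) or 4 (0.0678) and without PP242 72 h arrays 1 (0.0507), 3 (0.107) or 4 (0.138). Median and mean also differed in sign for HIF subunits (0.01 and -0.11, adjusted p = 0.873) and for fatty acid synthesis (0.03 and -0.03, adjusted p = 0.795), in which SREBF1 fell by 0.82. Cholesterol synthesis had 1 of 17 up (1 adjusted over the list alone, 2 with the block, adjusted p = 0.433), MYC targets 0 of 23 (0 adjusted over the list alone, 2 with the block, adjusted p = 0.114) and cytosolic ribosomal proteins 0 of 27 (0 adjusted over the list alone, 1 up and 1 down with the block, adjusted p = 0.764). For FEN1, ID1, SREBF1, TNFRSF10B and UVRAG, the other kept probe had no change at an unadjusted p under 0.05.

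**Figure D1:**
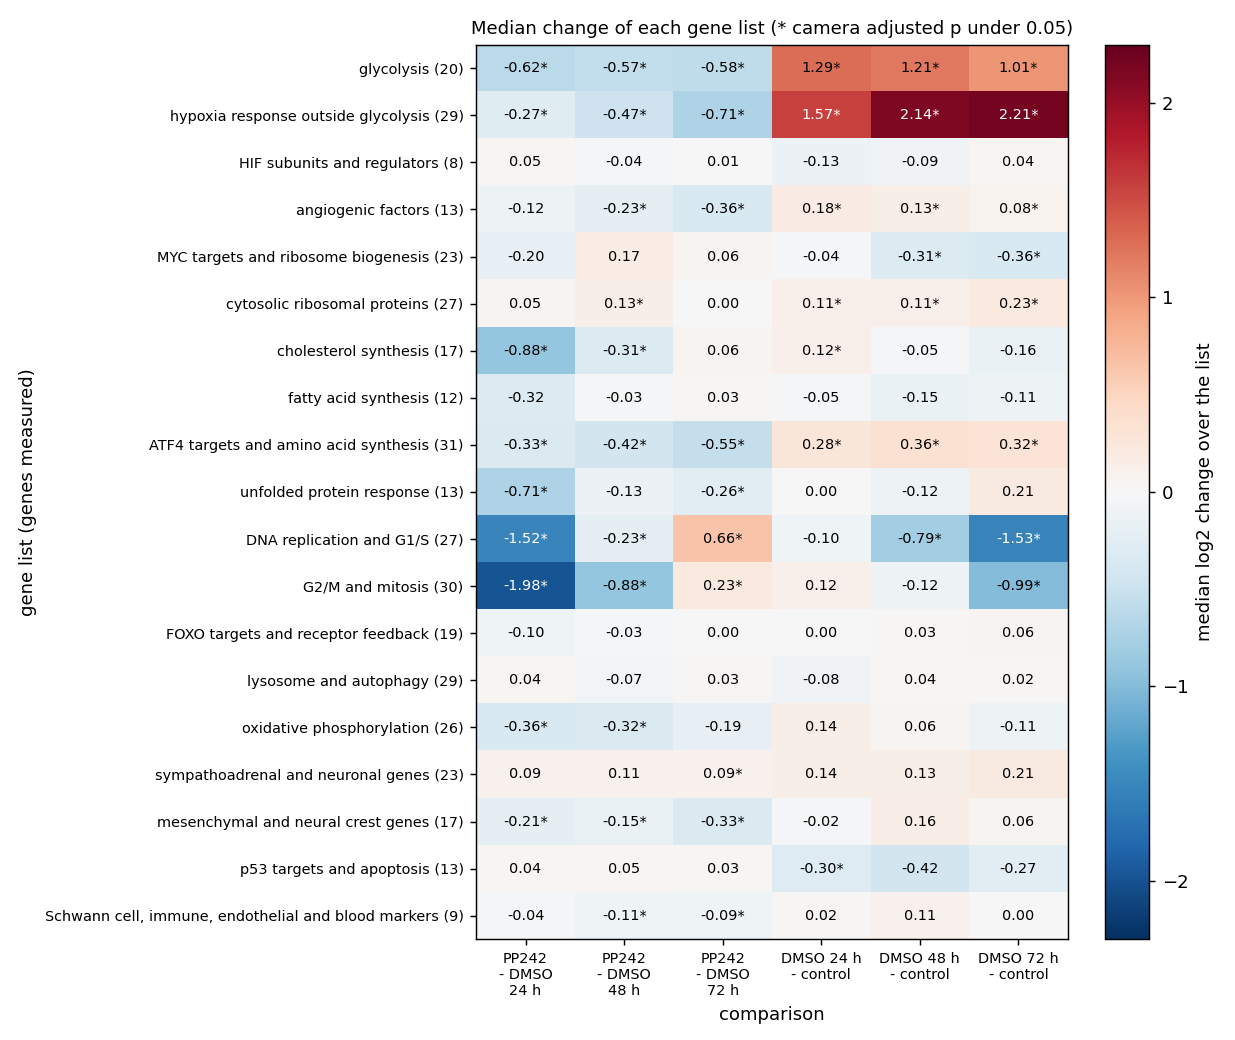
Median log2 change of each of the 19 gene lists (vertical axis) in the 6 comparisons of PP242 with DMSO and of hypoxia with the 0 h control (horizontal axis), with an asterisk where the camera adjusted p was under 0.05. The hypoxia list has a median of 2.21 in DMSO cells at 72 h and one of -0.71 for PP242 against DMSO at that time.

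The HIF and mTOR genes named in advance differed in their behaviour. EPAS1, which encodes HIF-2 alpha, had a log2 signal of 5.98 ± 0.33 (SD, n = 4) in the control, 6.31 ± 0.27 (SD, n = 3) in DMSO at 24 h, 7.41 ± 0.11 (SD, n = 4) at 48 h and 7.72 ± 0.22 (SD, n = 4) at 72 h. Against the control it was 0.33 higher at 24 h (SE 0.30, adjusted p = 0.662), rose by 1.44 at 48 h (adjusted p = 0.000571) and by 1.75 at 72 h (adjusted p = 2.26e-05). It rose by 1.41 between DMSO at 24 and 72 h (adjusted p = 0.00127). With PP242 its change was -0.62 at 24 h (SE 0.30, adjusted p = 0.154, blocked 0.00518), -1.17 at 48 h (SE 0.28, adjusted p = 0.00563) and -1.09 at 72 h (SE 0.28, adjusted p = 0.0107). Without PP242 72 h array 1 the last value was -0.82 with an adjusted p of 0.0624.

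HIF1A, the HIF-1 alpha gene, passed the threshold in 1 comparison without a block. Its signal was 9.05 ± 0.44 (SD, n = 4) in the control and 8.37 ± 0.34 (SD, n = 4) in DMSO at 48 h, a change of -0.68 (adjusted p = 0.0272). That call ended without control arrays 3 (-0.64, adjusted p = 0.0757) or 4 (-0.50, 0.128) and without DMSO 48 h arrays 1 (-0.63, 0.0864), 2 (-0.57, 0.106) or 3 (-0.70, 0.0542). It also ended with the mean of its kept probes (-0.20, 0.568) and in a fit of only the groups compared (0.0960). The changes were -0.31 at 24 h (adjusted p = 0.594) and -0.55 at 72 h (adjusted p = 0.0573). With PP242 HIF1A had values of 0.28 at 24 h (adjusted p = 0.451), 0.55 at 48 h (adjusted p = 0.0973, blocked 0.00466) and 0.65 at 72 h (adjusted p = 0.0507, blocked 0.00117). Without the arrays numbered 4 these had adjusted p of 0.0251 at 48 h and 0.00720 at 72 h, so its rise with PP242 at these times depends on how the sample number is treated. It also depends on the probe, since the other kept probes of HIF1A had no change at an unadjusted p under 0.05 at either time.

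VEGFA, the main angiogenic growth factor, had a signal of 6.80 ± 0.28 (SD, n = 4) in the control and 10.74 ± 0.19 (SD, n = 4) in DMSO at 72 h. Between DMSO at 24 and 72 h it rose by 1.84 (adjusted p = 2.24e-06). PP242 changed it by -0.31 at 24 h (SE 0.23, adjusted p = 0.386), -1.47 at 48 h (SE 0.21, adjusted p = 2.89e-05) and -1.88 at 72 h (SE 0.21, adjusted p = 4.70e-07). DDIT4, a hypoxia-induced inhibitor of mTORC1, rose in hypoxia by 2.56, 3.65 and 3.50 at 24, 48 and 72 h. It fell with PP242 at each time, with -1.22 at 24 h (adjusted p = 0.000517), -1.73 at 48 h (adjusted p = 6.99e-06) and -1.72 at 72 h (adjusted p = 5.69e-06). Between DMSO at 24 and 72 h it rose by 0.94 (adjusted p = 0.00755), with an adjusted p of 0.0540 without DMSO 24 h array 1 and 0.0674 with one median per array.

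MYCN had a signal between 14.01 ± 0.12 (SD, n = 4, DMSO at 72 h) and 14.36 ± 0.09 (SD, n = 3, DMSO at 24 h), and its changes with PP242 were -0.15, 0.01 and 0.15 at 24, 48 and 72 h (adjusted p = 0.652, 0.982 and 0.697). These signals lie near the highest measured on the arrays, where a change may be understated. The kinase gene MTOR had values of -0.18, 0.20 and 0.27 with PP242 (adjusted p = 0.652, 0.651 and 0.521), and -0.42 in hypoxia at 48 h (adjusted p = 0.207, blocked 0.0148). RPTOR, the mTORC1 scaffold, had a hypoxia change of -0.50 at 72 h (adjusted p = 0.0504). RPTOR and ARNT, the partner of the HIF alpha subunits, had no PP242 change larger in size than 0.22, with adjusted p of 0.522 or more. ARNT lay near background, above it on 2 of the 3 DMSO arrays at 24 h and on 3 of the 4 PP242 arrays at 24 and at 48 h. A change of ARNT may thus be understated. RICTOR, the mTORC2 scaffold, was above background on at most 2 arrays of a group and was not measured well enough to compare.

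**Figure D2:**
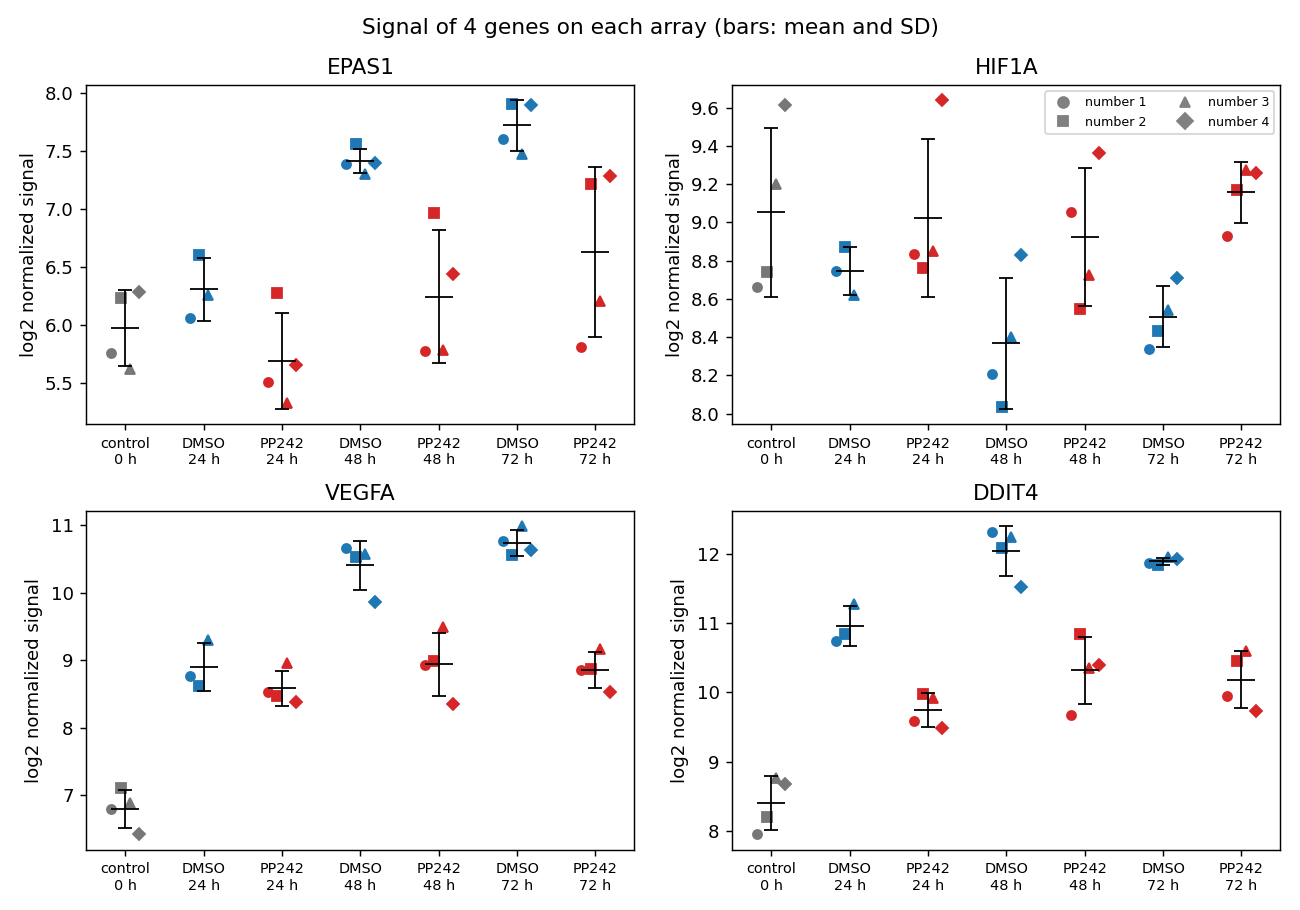
Log2 normalized signal (vertical axis) of EPAS1, HIF1A, VEGFA and DDIT4 on each array of the 7 groups (horizontal axis), with symbols for the sample numbers and bars for the mean and SD. VEGFA and DDIT4 lie lower with PP242 than with DMSO on every array at 48 and 72 h.

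The differences between PP242 effects at different times were tested directly. From 24 to 72 h the effect on cell division genes moved upward: DNA replication genes differed upward in 24 of 27 cases (26 adjusted over the list alone, median difference 2.13, adjusted p = 4.70e-34) and mitosis genes in 29 of 30 (29 adjusted over the list alone, median 2.14, adjusted p = 4.70e-34). FEN1 differed by 3.89 (SE 0.40, adjusted p = 2.48e-07), MCM10 by 3.85 and E2F2 by 3.84. Within treatments, the DNA replication list had a median of -1.503 between DMSO at 72 and 24 h, where 26 of 27 genes fell, and of 0.63 between PP242 at 72 and 24 h, where 13 rose. The mitosis list had medians of -1.05 in DMSO (25 of 30 fell) and 1.198 in PP242 (24 rose). Cholesterol synthesis differed upward in 9 members and downward in 1 of 17 (9 and 1 adjusted over the list alone, median 0.69, adjusted p = 4.45e-07). These 3 lists passed with an estimated correlation.

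The downward differences among named genes between 72 and 24 h of PP242 were led by ZNF467 at -3.97 (SE 0.22, adjusted p = 1.72e-12), DDIT3 at -3.81 and ATF5 at -3.65. DDIT3, added for 24 h after its values were seen, was higher with PP242 at 24 h (1.12, SE 0.26, adjusted p = 0.00249) and lower with it at 48 and 72 h. The hypoxia response differed downward in 7 members and upward in 1 of 29 (8 and 1 adjusted over the list alone, 11 and 1 with the sample number as a block, median -0.19, adjusted p = 0.0391; adjusted p = 0.514 with an estimated correlation). That call ended without DMSO 24 h array 1 (adjusted p = 0.105) or 2 (0.0542), PP242 24 h array 3 (0.0939), DMSO 72 h array 2 (0.0545) or PP242 72 h array 4 (0.103). In all 1920 genes had a different effect, 956 upward and 964 downward, and 3131 with the sample number as a block. The upward share went, with one median per array, from 49.8% to 67.8% (1141 and 542).

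From 24 to 48 h the PP242 effect differed for 640 genes, 339 upward and 301 downward. DNA replication genes differed upward in 23 of 27 cases (26 adjusted over the list alone, median 1.39, adjusted p = 2.74e-30), which passed with an estimated correlation. The mitosis list differed in 14 of 30 (23 adjusted over the list alone, median 1.09, adjusted p = 1.79e-19; adjusted p = 0.0892 with an estimated correlation). Cholesterol synthesis differed in 4 of 17 (8 adjusted over the list alone, 8 with the block, median 0.56, adjusted p = 4.03e-05; adjusted p = 0.0892 with an estimated correlation) and the unfolded protein response in 2 of 13 (5 adjusted over the list alone, 4 with the block, median 0.54, adjusted p = 0.000259; adjusted p = 0.0892 with an estimated correlation). MYC targets differed upward as a list (0 of 23 members, 0 adjusted over the list alone, 3 with the block, median 0.22, adjusted p = 0.0157; adjusted p = 0.12002 with an estimated correlation), with an adjusted p of 0.0558 without PP242 48 h array 1. The hypoxia response differed downward in 4 of 29 (7 adjusted over the list alone, 8 with the block, median -0.40, adjusted p = 0.000300; adjusted p = 0.135 with an estimated correlation). DDIT3 differed by -3.15 (SE 0.36, adjusted p = 6.40e-06) and KCNIP4 by -2.22. The gene count was 1504 with the sample number as a block, 345 without DMSO 24 h array 1, 340 without DMSO 24 h array 2, 406 without PP242 24 h array 3, 399 without DMSO 48 h array 3 and 408 without PP242 48 h array 2. With one median per array the upward share went from 52.97% to 64.1% (294 and 165).

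From 48 to 72 h the effect differed for 76 genes, 46 upward and 30 downward. The mitosis list differed upward in 7 of 30 (26 adjusted over the list alone, 19 with the block, median 1.11, adjusted p = 2.13e-31; adjusted p = 0.0659 with an estimated correlation), with the motor proteins KIFC1 at 1.55 and KIF11 at 1.54. The DNA replication list differed in 2 of 27 (19 adjusted over the list alone, 16 with the block, median 0.82, adjusted p = 2.26e-19; adjusted p = 0.0685 with an estimated correlation) and cholesterol synthesis in 0 of 17 (3 up and 1 down adjusted over the list alone and also with the block, median 0.42, adjusted p = 0.000590; adjusted p = 0.204 with an estimated correlation). Cytosolic ribosomal proteins differed downward in 1 of 27 (1 adjusted over the list alone, 2 with the block, median -0.16, adjusted p = 0.00246; adjusted p = 0.204 with an estimated correlation). ATF4 targets (0 of 31, 3 adjusted over the list alone, 2 with the block, median -0.13, adjusted p = 0.00673; adjusted p = 0.402 with an estimated correlation) lost their call without DMSO 48 h array 4 (0.0866) or PP242 48 h array 2 (0.128). The unfolded protein response (0 of 13, 1 adjusted over the list alone, 1 with the block, median -0.24, adjusted p = 0.0105; adjusted p = 0.294 with an estimated correlation) lost it without DMSO 48 h array 3 (0.0599) or PP242 48 h array 2 (0.101). ZNF467 differed by -1.78 (SE 0.21, adjusted p = 5.87e-05).

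The count of 76 rested on single arrays. It was 473 with the sample number as a block. Leaving out DMSO arrays at 48 h gave 2 (array 2), 49 (array 3) and 5 (array 4), and leaving out PP242 arrays at 48 h gave 20 (array 1), 186 (array 2) and 4 (array 4). At 72 h it was 2, 2, 6 and 138 without DMSO arrays 1, 2, 3 and 4, and 117, 2, 11 and 32 without PP242 arrays 1, 2, 3 and 4. The upward share went, with one median per array, from 60.5% to 87.5% (42 and 6).

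**Figure D3:**
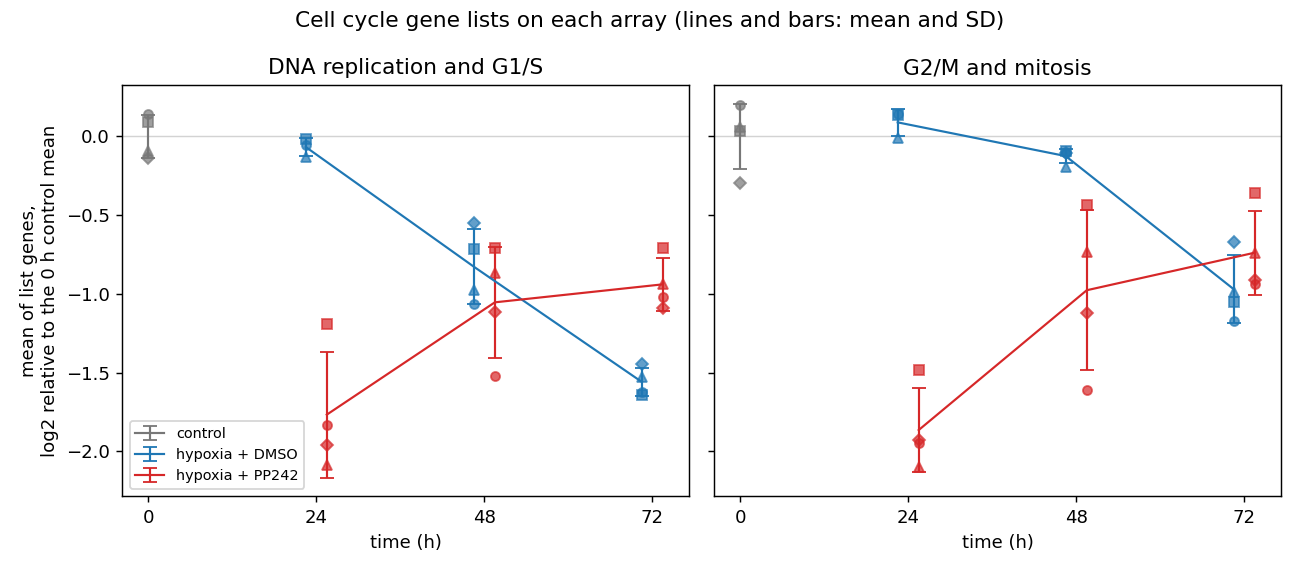
Mean log2 signal of the DNA replication and mitosis lists on each array, relative to the mean of the 0 h control (vertical axis), against time (horizontal axis, h), with symbols for the sample numbers, lines and bars for the mean and SD, and points shifted sideways for clarity. The DNA replication mean of DMSO cells goes from -0.07 at 24 h to -1.56 at 72 h, and that of PP242 cells from -1.77 to -0.94.

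Calls in the same direction at several times of PP242 were compared with the overlap expected for independent calls. Of the genes raised at 48 and at 72 h, 179 were shared where 19.1 were expected, and of those lowered 349 were shared where 40.0 were expected. Between 24 and 72 h, 114 were raised at both (expected 44.9), 159 were lowered at both (expected 78.3) and 203 were called in opposite directions (expected 121). At all 3 times 97 genes were raised and 135 lowered, KLF2, EGR1 and TXNIP among the raised and DDIT4, ADM and SLC2A1 among the lowered.

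Whether genes changed by hypoxia move the other way under PP242 was examined across all genes. The effects came from different times that share no array, and genes are not independent replicates. The PP242 effect at 72 h had a correlation of -0.564 (jackknife SE 0.0736) with the hypoxia effect at 48 h. PP242 at 72 h lowered 324 of the 850 genes raised by 48 h of hypoxia (46.5 expected) and raised 201 of the 900 lowered (30.8 expected). PP242 at 24 h showed the opposite sign, with correlations of 0.424 (SE 0.129) with hypoxia at 72 h and 0.210 (SE 0.167) with hypoxia at 48 h. It lowered 730 of the 1690 genes lowered by 72 h of hypoxia (191 expected) and raised 493 of the 1422 raised (148 expected). The glycolysis and hypoxia lists themselves were lower with PP242 at 24 h, so this sign is not that of these lists. The correlations of PP242 at 48 h were -0.247 (SE 0.196) with hypoxia at 24 h and -0.0877 (SE 0.123) with hypoxia at 72 h, and that of PP242 at 72 h with hypoxia at 24 h was -0.302 (SE 0.198). These are 6 correlations, computed over 12637 genes each. Without the genes of the hypoxia lists, that of PP242 at 72 h with hypoxia at 48 h was -0.555. That of PP242 at 24 h with hypoxia at 72 h was 0.461 without them. Of the 105 genes raised by 24 h of hypoxia, PP242 lowered 61 at 48 h (6.07 expected) and 63 at 72 h (5.75 expected). At each of these times it raised 3 of them. Of the 23 genes lowered, it lowered 3 and raised 3 at each time. The expected counts again assume independent calls.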

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

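The tests of a fall of DNA replication genes in the DMSO cells, of array brightness and of the state of the culture were chosen only after the results were seen, as was the requirement that a value pass its bound by more than its spread, and the tests without the arrays numbered 4 were added after the data were examined, with bounds written before their values were seen.

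The PP242 effect on DNA replication genes changed sign between 24 and 72 h, with a median difference of 2.13, though the rise at 72 h alone had an adjusted p of 0.0783 with an estimated correlation. Without the arrays numbered 4, which DMSO at 24 h lacks, the median difference was 2.05 (jackknife SE 0.290), which argues against the missing array as the cause. With one median per array the list median was 0.61 at 72 h (SE 0.190) and -1.82 at 24 h, which argues against the normalization. The difference is by construction the change of the PP242 cells between 72 and 24 h (median 0.63) minus that of the DMSO cells (-1.503), so these values show where it arises and test no explanation. What lowered these genes in the DMSO cells stays open, since time in hypoxia and time in culture are not separable here.

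Oxidative phosphorylation genes were lower with PP242 at 24 h (median -0.36). Without the arrays numbered 4 the median was -0.31 (jackknife SE 0.122, adjusted p = 0.000806), within its spread of the bound set beforehand. The fall thus remained without these arrays, which argues against the missing DMSO array as its whole source. Whether the missing array contributed a part cannot be told. Within the sample numbers 1 to 3 the medians of PP242 minus DMSO lay between -0.36 and -0.23, each lower with PP242, as an effect of the treatment requires. The call had an adjusted p of 0.305 with an estimated correlation, so it may rest on genes that vary together.

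Arrays numbered 4 differed from arrays numbered 1 in the same direction in every group that has both, with 1832 genes higher and 1686 lower in all 6 groups, where chance gives 1.56% of genes each way. Array brightness before normalization explained 5.53% of the variance of this difference (jackknife SE 2.96), which argues against it as the cause. Gene length had a Spearman correlation of 0.0909 with the difference (SE 0.0261). That lies within its spread of the bound set beforehand, so a part played by length cannot be told apart from other causes. The largest of the medians of the hypoxia, DNA replication and mitosis lists was -0.20 (SE 0.158), so the state of the culture cannot be told apart from other causes either. A shared slide, day or culture could also be the source, and the labels give none of these.

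Single arrays lay apart from the other 3 of their group in 11 of 180 Dixon tests, where chance gives about 1 in 20, that is 9 of them. For single genes these were HIF1A on PP242 24 h array 4 (9.64), VEGFA on DMSO 48 h array 4 (9.87), and MYCN on DMSO 48 h array 3 (14.01) and DMSO 72 h array 2 (14.19). For list means relative to the control they were HIF subunits on PP242 72 h array 2 (0.22), cytosolic ribosomal proteins on control array 4 (-0.21), mitosis on DMSO 48 h array 3 (-0.19), FOXO targets on PP242 24 h array 2 (0.080) and DMSO 48 h array 3 (-0.082), and mesenchymal genes on control array 4 (-0.22) and DMSO 48 h array 1 (0.34).

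The PP242 effect differed between 48 and 24 h, by a test of the difference itself, for 640 genes. Among lists it differed for the hypoxia response (-0.40), MYC targets (0.22), cholesterol synthesis (0.56), the unfolded protein response (0.54), DNA replication (1.39) and mitosis (1.09). With an estimated correlation DNA replication alone passed, and the others had adjusted p of 0.135 for the hypoxia response, 0.12002 for MYC targets and 0.0892 for each of the other 3. Among named genes it differed for DDIT3 (-3.15), KCNIP4 (-2.22), ZNF467 (-2.19), the linker histone H1-2 (-2.12), FEN1 (2.52), UHRF1 (2.41), E2F2 (2.39) and MCM10 (2.35).

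Between 72 and 24 h it differed for 1920 genes, and for the hypoxia response (-0.19), cholesterol synthesis (0.69), DNA replication (2.13) and mitosis (2.14). The hypoxia response had an adjusted p of 0.514 with an estimated correlation and lost its call without DMSO 24 h array 1 (0.105) or 2 (0.0542), PP242 24 h array 3 (0.0939), DMSO 72 h array 2 (0.0545) or PP242 72 h array 4 (0.103), while the other 3 lists passed with an estimated correlation. The named genes were ZNF467 (-3.97), DDIT3 (-3.81), ATF5 (-3.65), MT1G (-3.57), FEN1 (3.89), MCM10 (3.85), E2F2 (3.84) and MELK (3.72).

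Between 72 and 48 h it differed for 76 genes, and for cytosolic ribosomal proteins (-0.16), cholesterol synthesis (0.42), ATF4 targets (-0.13), the unfolded protein response (-0.24), DNA replication (0.82) and mitosis (1.11). With an estimated correlation none of these 6 lists passed, with adjusted p of 0.204, 0.204, 0.402, 0.294, 0.0685 and 0.0659 in that order. The named genes were MT1X (-2.14), MT1E (-1.91), ZNF467 (-1.78), MT1F (-1.64), KIFC1 (1.55), KIF11 (1.54), GPX3 (1.49) and CKAP2L (1.48). In a fit of only the groups compared, each of these 8 genes but ZNF467 had an adjusted p between 0.0858 and 0.116.

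Probes without a gene name, outside every comparison of genes, also passed the threshold. Of 14822 such probes 1219 passed for PP242 against DMSO at 24 h, 479 at 48 h and 330 at 72 h, and 33, 646 and 1523 for hypoxia of 24, 48 and 72 h against the control.

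Over all 35 splits of the arrays, the real split alone gave as many genes in each of the 7 comparisons of groups. These splits treat all arrays as exchangeable, which arrays paired by sample number are not, so they do not settle whether chance is excluded there. For PP242 against DMSO the real count and the highest other were 2741 and 2186 at 24 h, 1291 and 2 at 48 h, and 1124 and 0 at 72 h. For hypoxia against the control they were 128 and 59 at 24 h, 1750 and 217 at 48 h, and 3112 and 1 at 72 h, and for DMSO at 72 h against 24 h they were 2098 and 768. Among the 8 splits that part as many pairs of sample numbers as the real one, in comparisons where the numbers pair the arrays, the highest others were 422, 1 and 0 for PP242, 29 and 8 for hypoxia at 24 and 48 h, and 768 for DMSO over time, but 8 splits are too few for a share under 5 in 100. The highest others at 24 h and over time leave 1 array out of place, PP242 24 h array 2 among DMSO for 2186 and DMSO 72 h array 4 among the 24 h arrays for 768, so most of the real contrast stays in them. The 217 of hypoxia at 48 h came from a split that exchanges control array 2 and DMSO 48 h array 4.

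For the differences between PP242 effects, 100 draws of treatment labels within each time were made, the real one included. As many genes as the real 640 between 48 and 24 h came in 4 draws (highest other 1507), as many as the real 1920 between 72 and 24 h in 1 draw (highest other 1379), and as many as the real 76 between 72 and 48 h in 3 draws (highest other 633). These shares are under 5 in 100, but the draws reverse or mix the real PP242 effects at a time and do not remove them, so they do not settle whether chance is excluded for a difference of effects. The draw with 1507 genes exchanges 3 labels at 48 h and 0 at 24 h, and that with 1379 exchanges 2 at 72 h and 0 at 24 h. The draw with 633 genes exchanges all 4 labels at 48 h and 1 at 72 h, which reverses the real PP242 effect at 48 h. Among the draws that part as many pairs of sample numbers as the real one, the highest others were 0 in 4 draws between 48 and 24 h, 0 in 8 draws between 72 and 24 h, and 633 in 5 draws between 72 and 48 h, too few draws for a share under 5 in 100. The real count of 76 became 1 without the arrays numbered 4 and 1 in a fit of only the groups compared.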

How the results depend on the processing

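The fits without every array numbered 4 were added after the data were examined, and the other alternatives were set beforehand.

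Camera with an estimated correlation called 4 lists for PP242 at 24 h (main 9), 6 at 48 h (main 11) and 4 at 72 h (main 10), and 3 for hypoxia at 24 h (main 7), while fry called 16 for PP242 at 24 h.

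The sample number as a block gave 2506 genes for PP242 at 48 h (main 1291), 2164 at 72 h (1124), 361 for hypoxia at 24 h (128), 2988 at 48 h (1750), 3203 for DMSO at 72 h against 24 h (2098), and 1504, 3131 and 473 for the PP242 effect at 48 against 24 h, 72 against 24 h and 72 against 48 h (640, 1920 and 76). Array weights gave 195 for hypoxia at 24 h, 3416 for DMSO over time, 1144 for the PP242 effect at 48 against 24 h and 158 at 72 against 48 h. A fit of only the groups compared gave 67 and 955 for hypoxia at 24 and 48 h. With every kept probe as its own unit, hypoxia at 72 h had 4825 probes (main 3112 genes). The cause of these moves was not tested.

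The PP242 effect at 72 against 48 h, with 76 genes, moved most: 124 without background correction, 127 with an offset of 50, 48 with one median per array, 144 in the authors' table, 135 with the strict filter, 14 probes with every kept probe, 1 without the arrays numbered 4 and 1 in a fit of only the groups compared.

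Leaving out single arrays gave 80 to 145 genes for hypoxia at 24 h (lowest without DMSO 24 h array 3, highest without control array 2), 1360 to 1843 for DMSO over time (without DMSO 24 h arrays 2 and 3), 340 to 770 for the PP242 effect at 48 against 24 h (without DMSO 24 h array 2 and PP242 24 h array 2), and 2 to 186 at 72 against 48 h (without DMSO 48 h array 2, among others, and PP242 48 h array 2).

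Of the 416 results of named genes past the threshold, with 8374 values under the alternatives, 8005 kept the call, 368 lost it and 1 was reversed: RPL13 in hypoxia at 48 h went from 0.59 to -0.025 (adjusted p = 0.946) with the mean of its kept probes. Of 76 list calls, with 1842 values, 1727 kept the call, 115 lost it and 0 were reversed. Of these values 702 come from leaving out single arrays, where 32 lost the call. Camera with an estimated correlation ended 42 of the 76 calls, so the pooled count hides the setting that mattered most. Without the arrays numbered 4 the calls lost were mesenchymal genes (adjusted p = 0.0626, PP242 24 h), DNA replication (0.404, PP242 48 h), sympathoadrenal genes (0.0855, PP242 72 h), cytosolic ribosomal proteins (0.109 and 0.0751, hypoxia 24 and 48 h), p53 targets (0.189, hypoxia 24 h) and ATF4 targets (0.344, PP242 effect at 72 against 48 h). A fit with the slide as a block was not run.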

Other observations

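The test of the array-by-array response to PP242 was chosen only after the result was seen, and the correlations without the arrays numbered 4 were added after the data were examined.

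The PP242 profile at 24 h resembled that of DMSO cells at 72 h of hypoxia across genes (correlation 0.424), and genes are not independent replicates. A shared fall of DNA replication and mitosis genes could produce such a resemblance. Without the 27 and 30 genes of both lists the correlation was 0.399, without the arrays numbered 4 it was 0.506, and without both it was 0.481 (jackknife SE 0.0594). Leaving out the lists thus lowered it slightly, which argues against the genes of these lists as its whole source. Cell division genes outside the lists were not left out, so a wider shared fall stays open. Without the arrays numbered 4 the correlation of the PP242 effect at 24 h with hypoxia at 48 h was 0.320, against 0.210 with all arrays.

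The PP242 response of each array, as a percentage of that of the other PP242 arrays at its time, was 98.2, 73.0, 112.9 and 109 for arrays 1 to 4 at 24 h over 1884 genes. It was 117, 60.4, 90.6 and 103 at 48 h over 3389 genes, and 95.4, 80.8, 90.1 and 97.3 at 72 h over 3304 genes. The array numbered 2 had the lowest value at each of the 3 times, and the cause was not tested.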
